A study of Triticum polonicum with 10 samples.

How the data were processed

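Root transcripts of dwarf Polish wheat (Triticum polonicum, a tetraploid wheat whose chromosomes belong to the A and B subgenomes) were measured by RNA sequencing in 10 libraries, 1 for each of 10 treatments. Per the labels, the seedlings were 4 weeks old, the treatment lasted 1 week, RNA was taken with Trizol, and libraries were made with an Illumina TruSeq RNA kit. The design text names 3 biological replicates per treatment, but each treatment has 1 library and 1 column. Whether that library pools 3 plants or cultures is not given in the sources used here.

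Each library was assigned to its group from its treatment text and its title code. In 6 libraries (control, cadmium, and FeCl3 at 50 or 200 µM without or with 80 µM CdCl2) both sources gave the same treatment. Of the 4 Fe2(SO4)3 libraries, 1 had a code and a text that matched, 200 µM without cadmium. The other 3 did not match. The library coded B50CK was described as 200 µM with cadmium, the one coded B50Cd as 50 µM without cadmium, and the one coded B200Cd as 50 µM with cadmium. These 3 libraries were assigned to their iron salt alone and are named by their codes below. They entered the comparison of the salts, where 4 libraries of each salt cover both doses with and without cadmium under either reading. Doses are in µM of the salt, and by its formula Fe2(SO4)3 carries more iron per unit than FeCl3. Equal doses therefore did not supply equal iron, and the form of the salt cannot be separated from the amount of iron.

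The deposited count table holds whole-number counts per gene ID, and its column names matched the title codes. Bowtie2 2.0.6 and TopHat2 2.0.12 are named in the submitters' processing notes. The counting program, the genome build, the filters, the strand setting and the treatment of reads that match several genes are not given in the sources used here. The A and B subgenomes carry near-identical copies of many genes, so counts of such copies are uncertain. The authors also deposited FPKM values for the same genes and libraries. Dividing each library's CPM (counts scaled to the library total) by its FPKM gave 1 length per gene, with a largest difference of 0 bp between libraries over 94295 genes, so the FPKM were the counts scaled by gene length and library total. All of these lengths were whole within 0.01 bp. Each table listed 274924 gene IDs, of which 107370 had a count in at least 1 library. No row named anything other than a gene.

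Most IDs follow the bread wheat pattern, which gives a chromosome, a subgenome letter, a number and, for some, the suffix LC. Others have the form Novel00213. The files do not pair IDs with gene names or descriptions, and no annotation was used here. The 25 lists of protein families fixed before the data were examined (metal-binding peptides, iron uptake, glutathione synthesis, metal transporters and others) therefore could not be matched to any gene, and no result is given for them. In their place, 20 groups that the IDs define (subgenomes A, B and D, unplaced IDs, LC IDs, IDs of the Novel00213 form and the 14 chromosomes of A and B) were tested with camera in each of the 5 comparisons, with a preset and with an estimated correlation between genes. These groups were chosen after the files had been seen. Adjusted p-values of groups cover the 20 groups of a comparison.

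The tests, the alternatives and the rule for naming genes were fixed before the data were examined, apart from those stated to have been added. Counts were tested with edgeR 4.0.16 (quasi-likelihood test, TMM normalisation, filterByExpr defaults) and Benjamini-Hochberg adjustment at 0.05, under R 4.3.3. The cadmium effect and the effects of 50 and 200 µM FeCl3 came from 1 additive fit of 6 libraries, with cadmium and the 3 iron supplies as terms. The 3 cadmium pairs at different iron supplies thus served as the replication, with 2 residual degrees of freedom, and any true change of the cadmium effect between supplies counts as error. The change of the cadmium effect with iron was tested in the same libraries as an interaction with the FeCl3 dose, per 100 µM. The salts were compared as 4 against 4 libraries without covariates. Nothing in the labels says that any 2 libraries are separate plants of 1 treatment, so p-values measure the spread between these libraries.

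Because the IDs carry no names, at most 2 IDs per direction are named in each comparison. The rule took the largest fold among genes past the threshold, or the smallest p where no gene passed. It asked for a mean of at least 5 CPM and, where pairs or groups exist, the same direction in every pair or no overlap between the groups. Log2 folds are given with a standard error derived from the test, and CPM per library from the counts. That error is the size of the log2 fold divided by the square root of the quasi-likelihood F. Patterns between libraries used log2(CPM + 0.5) of genes with a mean of at least 5 CPM. Those patterns were chosen after the data had been seen. Calculations also used limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

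The procedure was tested on counts simulated from the real means, library totals and dispersions, with 50 genes changed at each of 4 sizes. Dispersions were taken from their trend with expression level, so differences in spread between genes of like level were left out. Changed genes were drawn from those with a mean above 20 counts. The shares recovered hold for these settings and may be too high for real genes. Genes changed 4-fold were recovered in 48% of cases for cadmium (52765 genes), 20% for 50 µM FeCl3 (52769), 22% for 200 µM FeCl3 (52872) and 76% for the salts (48968). Genes changed 16-fold were recovered in 98%, 86%, 94% and 100% of cases in the same order. For the interaction none of the simulated changes was recovered at any size (52979 genes), although 100% of the 16-fold changes were estimated in the right direction. With 4-fold changes put into the 3 cadmium pairs, 138 of 200 genes were at least 2-fold apart in every pair in the simulated direction. These 200 were drawn from genes with a mean above 200 counts. Of the 25355 simulated genes, 57 unchanged ones were at least 2-fold higher and 36 at least 2-fold lower in every pair, and a mixed pattern held 32.5 on average.

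Library totals ran from 13635628 to 19320820 counts. A count of 0 allowed up to 3 counts, which is 0.155 to 0.220 CPM depending on the library. Such limits and Poisson intervals cover counting error only. Alternatives were DESeq2 in place of edgeR, DESeq2 size factors in place of TMM, no filter or a filter of 1 CPM in 2 libraries, and limma on log2(FPKM + 1). Further alternatives were the fit without the iron term, a log dose in the interaction, dose and cadmium as covariates of the salts, each library or pair left out, and the sulfate libraries added to the cadmium fit under both readings of their labels. Cadmium fits of the 8 iron-fed libraries or of the 4 sulfate libraries alone, and other settings of the pair patterns, were added after the data had been seen.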

Results

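The series addressed how 2 chemical forms of iron fertiliser alter the response of dwarf Polish wheat roots to cadmium. Seedlings received no iron salt, FeCl3 at 50 or 200 µM, or Fe2(SO4)3, and each supply was given without or with 80 µM CdCl2. Below, without iron or no iron means that no iron salt was added. There was 1 library per treatment, so no treatment has a spread of its own. Total counts were lowest in the control, at 13635628, and highest in the library with cadmium and no iron, at 19320820. Between 73346 and 81068 genes had a count in each library.

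Root transcripts came almost entirely from genes of the A and B subgenomes. IDs of subgenome A held 48.0% to 48.9% of the counts and those of subgenome B 46.0% to 47.0%, while IDs of subgenome D, which is foreign to a tetraploid wheat, held 1.16% to 1.25%. IDs of the Novel00213 form took 2.22% to 3.60%, and the 10 most abundant genes of a library took 1.58% to 3.13%. Libraries were set side by side by the standard deviation (SD) of the log2 ratio over 25616 genes. The closest pairs were the sulfate libraries coded B50Cd and B200Cd (SD 0.48) and the 2 FeCl3 libraries with cadmium (SD 0.48). The control stood farthest from the rest, with a mean SD of 1.22 to the other libraries, against 0.80 to 0.95 for each of the others.

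**Figure D1:**
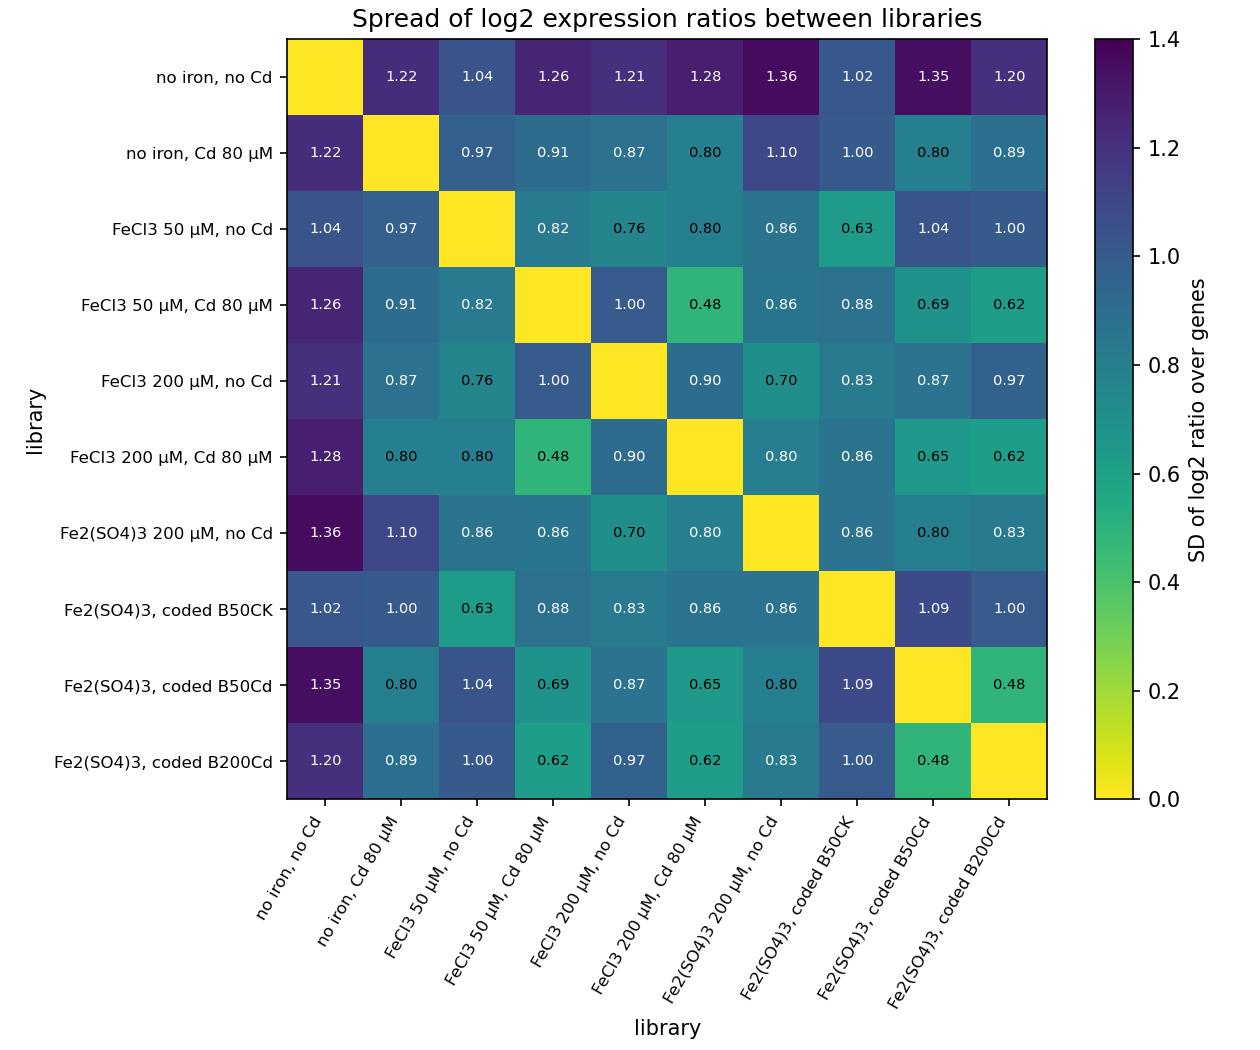
Each cell gives the SD of the log2 expression ratio between 2 of the 10 libraries over 25616 genes, with libraries on both axes and darker cells for larger spreads. The 7 largest values, 1.20 to 1.36, all lie in the row of the control (no iron, no Cd), and the smallest values, 0.48, join the 2 FeCl3 libraries with cadmium and the sulfate libraries coded B50Cd and B200Cd.

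Levels of a limited set of genes differed widely between the libraries with and without cadmium at every FeCl3 supply. TraesCS4B01G017600 was at 0.51, 0.60 and 1.57 CPM without cadmium (0, 50 and 200 µM FeCl3) and at 41.6, 46.7 and 48.8 CPM with it, a log2 fold of 5.86 ± 0.43 (SE, 3 pairs). TraesCS6B01G162700 was higher with cadmium in 3 of 3 pairs, with a log2 fold of 4.60 ± 0.40 and 22.5, 9.60 and 13.4 CPM in the cadmium libraries. Lower with cadmium in 3 of 3 pairs were TraesCS3B01G059900, from 40.7 to 1.81 CPM without iron (log2 fold -4.77 ± 0.58), and TraesCS4A01G334000, from 35.1 to 2.64 CPM without iron (log2 fold -3.24 ± 0.39). Both of these lower genes were also low in the sulfate library at 200 µM without cadmium, at 0.30 and 1.00 CPM.

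**Figure D2:**
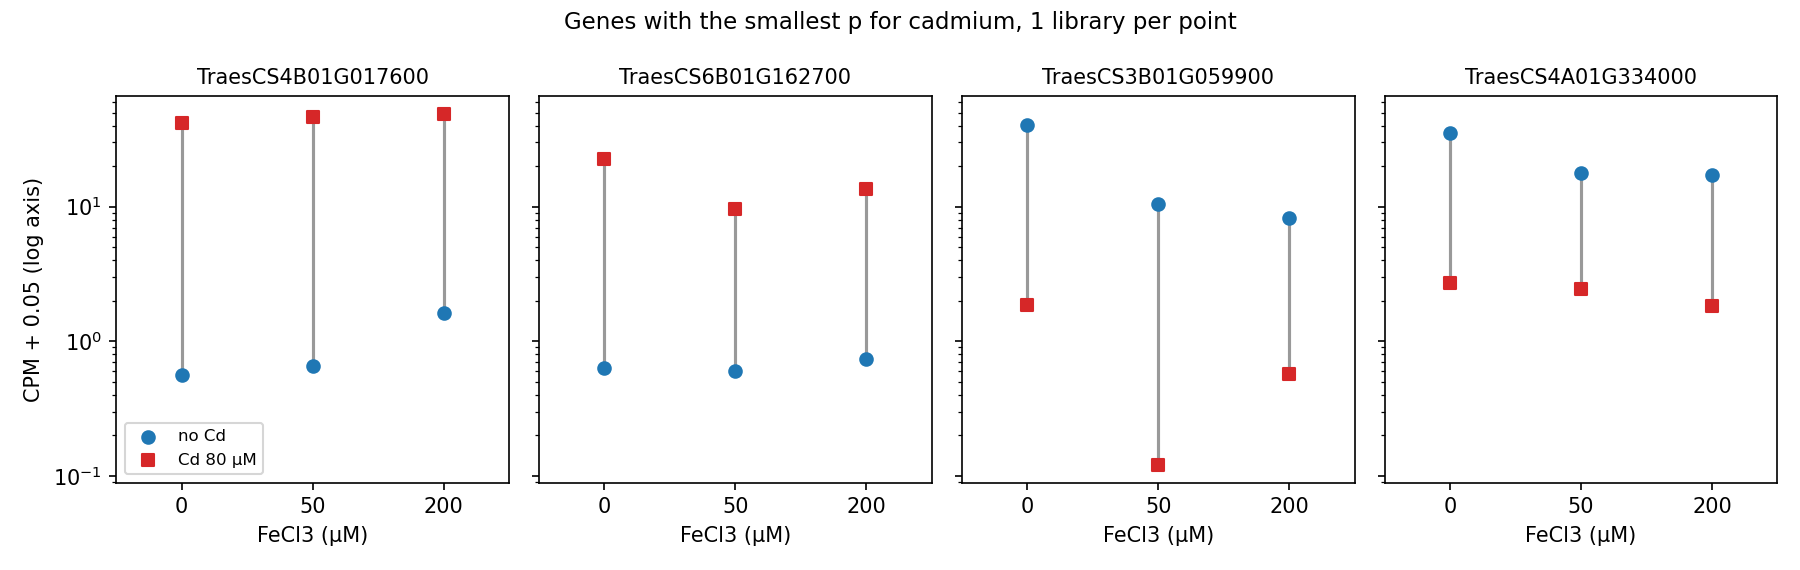
CPM plus 0.05 on a log axis against the FeCl3 supply (µM) for the 4 genes named for cadmium, with 1 library per point, blue circles without and red squares with 80 µM CdCl2, and grey lines joining the pair at each supply. TraesCS4B01G017600 lies between 41.6 and 48.8 CPM in the 3 cadmium libraries and at or below 1.57 CPM in the others.

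Of 25565 genes, 637 were at least 2-fold higher and 206 at least 2-fold lower with cadmium in each of the 3 pairs. In counts simulated with no cadmium effect on them, 57 unchanged genes were higher and 36 lower in every pair. The 6 mixed patterns of direction held 328 genes between them, of which 236 were lower with cadmium without iron and higher at both FeCl3 doses. A mixed pattern held 4 to 236 genes, 54.67 on average, against 32.5 on average in the simulation. The simulated counts are therefore only a rough reference for 637 and 206. At a 4-fold limit the counts were 125 higher, 22 lower and 18 mixed. The share higher in every pair was 2.62% of subgenome A IDs, 2.52% of B, 2.82% of D and 5.06% of unplaced IDs, and 8 of 1279 IDs of the Novel00213 form were higher. Differences between these shares were not tested. Across genes, which are not independent replicates, the cadmium log2 folds at 50 and 200 µM FeCl3 had r = 0.544. The fold without iron was less related to either, with r = 0.312 for 50 µM and 0.150 for 200 µM. For 0 against 200 µM, Spearman's rho was 0.0509 and 50.1% of genes had the same sign. The pair without iron holds the control, the library farthest from the others. Its log2 folds had an SD of 1.23, against 0.82 at 50 µM and 0.91 at 200 µM. A deviation of the control alone cannot be told apart here from a change of the cadmium effect with iron, also for the 236 genes.

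**Figure D3:**
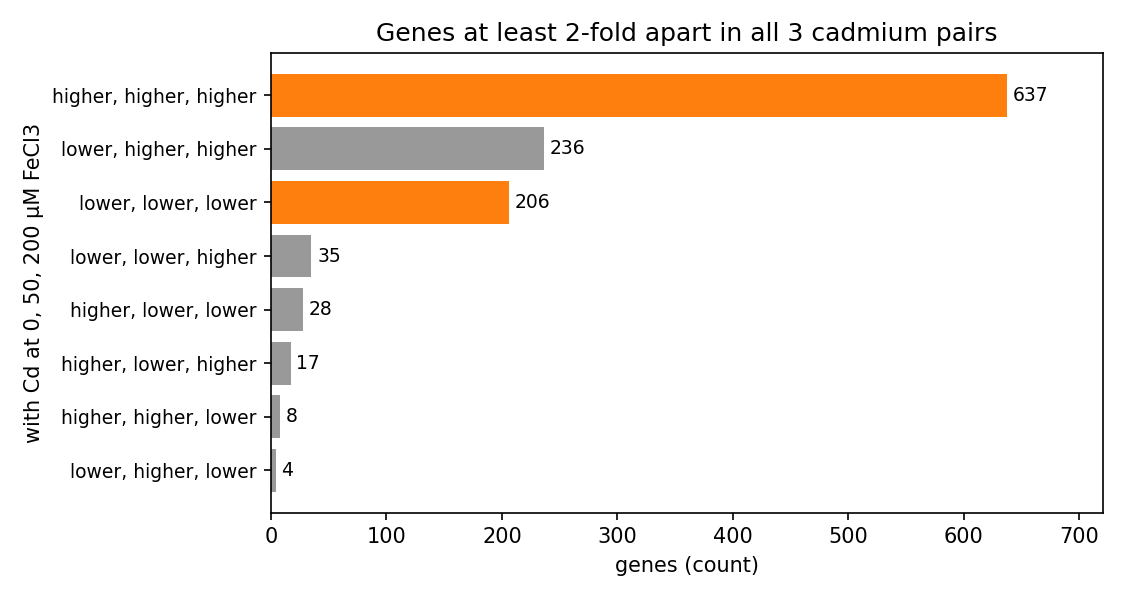
Number of genes at least 2-fold apart between the libraries with and without cadmium in all 3 pairs, by direction at 0, 50 and 200 µM FeCl3. Orange bars are the 2 patterns with 1 direction throughout, with 637 and 206 genes, and grey bars are the mixed patterns, the highest of which holds 236.

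In the test over the 3 pairs, no gene of 55236 passed the threshold with edgeR (smallest adjusted p = 0.113, which the 4 named genes share). At an unadjusted p under 0.05 there were 6624 genes, 4060 of them higher with cadmium, where chance alone gives 2762. DESeq2 called 2371 genes in the same libraries and limma on FPKM called 25, and none of the 20 ID groups passed with camera. The edgeR count was 3155 without a filter on low counts, 749 without the pair at 0 µM FeCl3, and 8 without the iron term. Without the pair at 50 µM, 3788 genes were left at an unadjusted p under 0.05. Adding the sulfate libraries gave 1453 genes when read by their title codes and 0 genes (3289 unadjusted) when read by their treatment text.

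Iron supply was compared at each FeCl3 dose with the 2 libraries that received no iron salt. At 50 µM, TraesCS3A01G509600 was at 43.0 CPM without and 6.17 CPM with cadmium, against 0.66 and 0.21 CPM without iron (log2 fold 5.68 ± 0.49). TraesCS4B01G299500 had 1 count in each library without iron and was at 5.55 and 9.88 CPM at 50 µM, a ratio of 123 over both libraries (95% exact counting interval 33.6 to 1020). Levels were lower with iron for TraesCS5B01G257700, from 4.18 to 0.22 CPM without cadmium and from 41.8 to 2.17 CPM with it (log2 fold -3.95 ± 0.48). TraesCS6B01G383500 was at 0.66 CPM without and 34.5 CPM with cadmium when no iron was given, and had 0 counts in both libraries at 50 µM. Its measured level without iron was 4 times the limit of 3 counts per library without cadmium, and 164 times that limit with it. These ratios leave out the counting error of the level without iron, which rested on 9 counts in the control.

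At 200 µM FeCl3 the rule named TraesCS3A01G509600 (log2 fold 5.16 ± 0.48) and TraesCS4B01G299500 (ratio 145, interval 39.7 to 1200) again among the higher genes. The lower ones were TraesCS2A01G149900, from 267.5 to 38.5 CPM without cadmium and from 44.2 to 5.0 CPM with it (log2 fold -2.96 ± 0.42), and TraesCS2B01G175100, from 140.7 to 23.3 and from 30.0 to 4.82 CPM (log2 fold -2.61 ± 0.38). Both of these genes were also lower with cadmium than without it at each FeCl3 supply. In single pairs of libraries, 1322 genes were at least 2-fold higher at 50 µM than without iron both without and with cadmium, 297 were lower in both, and 684 went opposite ways. At 200 µM the numbers were 769, 412 and 991. Going from 50 to 200 µM separated libraries less in the presence of cadmium (SD of log2 ratios 0.49) than in its absence (0.76), a difference with no replicate check.

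No gene passed the threshold with edgeR at either dose (smallest adjusted p = 0.408 at 50 µM and 0.528 at 200 µM). At an unadjusted p under 0.05 there were 5093 genes at 50 µM (3346 higher) and 5125 at 200 µM (3043 higher), where chance alone gives 2762. DESeq2 called 843 and 494 genes, limma on FPKM called 0 at both doses, and edgeR without a filter on low counts called 1374 and 1160. In camera, subgenome D IDs were shifted up at 50 µM (2764 genes, median log2 fold 0.36, adjusted p = 0.01) and IDs of the Novel00213 form down (4408 genes, median -0.30, adjusted p = 0.00722). Neither call held with an estimated correlation (adjusted p = 0.465 and 0.909), and no group passed at 200 µM. The doses share the libraries without iron. Their log2 folds had r = 0.792 and a covariance of 0.448 over 25565 genes. In 20 simulations with no iron effect the values were 0.498 and 0.171, and the covariance difference was 0.277. These simulations gave every library the same spread, while the control, a shared library, stood farthest from the others. Extra spread in a shared library could raise both values, so the difference cannot be read as an iron effect. At an unadjusted p under 0.05 the doses shared 1695 higher and 855 lower genes. In simulations with no iron effect, lists of the same lengths shared a mean of 1090 and 275 genes, and independent lists would share 184 and 65.8. The simulated lists overlapped more than independent ones, so the shared libraries account for part of the overlap. How large a part cannot be told, because the simulations gave every library the same spread. With no library in common, the fold at 50 µM without cadmium and that at 200 µM with cadmium had r = 0.285, and the reverse pairing had r = -0.0547. The fold at 1 dose without cadmium had r = 0.198 (50 µM) and 0.0562 (200 µM) with that in its presence.

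Single libraries decided these counts. Without the control, edgeR called 1293 genes at 50 µM and 121 at 200 µM, with 9306 unadjusted at 50 µM. Without the cadmium library that had no iron, it called 2004 and 3360, with 10546 and 13002 unadjusted. Without the FeCl3 library of the same dose and no cadmium, 1 and 0 genes were called, with 1856 and 2140 unadjusted. In each of these fits 1 of the iron supplies was left with a lone library, assumed to vary like the others.

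The next question was whether the cadmium effect changed with the FeCl3 dose. TraesCS1B01G277000 was at 25.1 CPM in the control and 1.03 CPM with cadmium, but at 0.068 CPM (1 count) and 5.17 CPM at 200 µM FeCl3, so its log2 cadmium effect was higher by 5.54 ± 0.65 per 100 µM. For TraesCS2B01G185700 the slope was 4.12 ± 0.51. Slopes below 0 were found for TraesCS1A01G156100 (-1.77 ± 0.36), which was at 4.33 and 34.99 CPM without iron and at 53.1 and 24.9 CPM at 200 µM, and for TraesCS6B01G005000 (-1.95 ± 0.40, and -3.12 without the 200 µM library that had no cadmium). None of the 55236 genes passed with edgeR (smallest adjusted p = 0.999), and 2044 had an unadjusted p under 0.05, fewer than the 2762 that chance gives. In simulated counts this test recovered no changed gene even at 16-fold, so the lack of calls does not answer the question. DESeq2 called 75 genes, limma on FPKM 0, and edgeR without a filter on low counts 484 (4386 unadjusted). The unadjusted count was 1064 without the cadmium library that had no iron. It was 3300 and 3123 without the 50 µM libraries (no cadmium, cadmium), 4260 and 3077 without those at 200 µM, and 3474 with a log dose. No ID group passed.

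The salts were compared as 4 FeCl3 against 4 Fe2(SO4)3 libraries, at doses given in µM of the salt rather than of iron. TraesCS7B01G103900 was at 7.09 to 14.3 CPM with chloride and 1.71 to 3.29 CPM with sulfate (log2 fold -1.90 ± 0.33, sulfate against chloride, n = 4 libraries each). For TraesCS2B01G566000 the ranges were 10.98 to 17.6 and 3.52 to 6.72 CPM (log2 fold -1.68 ± 0.30). Higher with sulfate were TraesCS7B01G242100LC, at 4.36 to 10.9 against 1.89 to 3.68 CPM (log2 fold 1.52 ± 0.34), and Novel00213, at 6.79 to 14.1 against 3.04 to 5.22 CPM (log2 fold 1.33 ± 0.30). In camera, IDs of the Novel00213 form (4019 genes, median log2 fold 0.19, adjusted p = 4.82e-06) and LC IDs (7766 genes, median 0.19, adjusted p = 1.19e-05) were shifted up with sulfate. Neither held with an estimated correlation (adjusted p = 0.323 for each).

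None of 50484 genes passed the threshold between the salts with edgeR (smallest adjusted p = 0.999), and 1803 had an unadjusted p under 0.05, fewer than the 2524 that chance gives. That fit counted differences of dose and cadmium as spread within each salt, which can lower the count. DESeq2 called 17 genes and limma on FPKM 0. The edgeR count was 1 without the FeCl3 library at 200 µM with cadmium. The unadjusted count was 1022 without the FeCl3 library at 50 µM without cadmium, 3794 without that at 200 µM without cadmium, 5220 without the library coded B50CK and 1143 without that coded B200Cd. With dose and cadmium as covariates it was 3809 of 56571 genes by the title codes, a share above 0.05. By the treatment text it was 2084 of 56571, a share below 0.05. Without a filter on low counts it was 4083.

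At 200 µM without cadmium both salts have a library whose labels match. These 2 libraries had an SD of log2 ratios of 0.70, the 8th smallest of the 45 pairs of libraries. In the sulfate library 262 genes were at least 4-fold higher and 112 at least 4-fold lower. The widest ratios belonged to Novel03361, at 61.4 CPM with sulfate (95% exact Poisson interval 57.7 to 65.3) and 0.409 CPM with chloride (0.150 to 0.890), and to TraesCSU01G336000LC, at 0.177 CPM (0.0365 to 0.518) and 68.9 CPM (64.7 to 73.3). These values compare 2 libraries that differ in the iron supplied as well as in the salt, with no replicate check of the salts.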

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

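Library measures and the genes named for the salts were examined for a library far from the others among the 4 FeCl3 and among the 4 Fe2(SO4)3 libraries. Of 32 such groups 2 held one, where chance gives about 1.6. The FeCl3 library at 50 µM without cadmium had the lowest share of counts in its 100 most abundant genes, 9.80%, against 10.7% to 10.8% in the other FeCl3 libraries. The FeCl3 library at 200 µM without cadmium had the highest share of counts in LC IDs, 6.80%, against 5.84% to 5.98%. No explanation was tested for either.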

How the results depend on the processing

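No gene passed the threshold in any comparison as tested, so an alternative could only add calls; the cause was not tested. DESeq2 called 2371 genes for cadmium, 843 and 494 for 50 and 200 µM FeCl3, 75 for the interaction and 17 for the salts. Without a filter on low counts edgeR called 3155, 1374, 1160 and 484 in the first 4 of these and 0 for the salts. For cadmium, limma on FPKM called 25 and the fit without the iron term 8. With the sulfate libraries read by title code the count was 1453, and in fits added after seeing the data 1848 (8 iron-fed libraries) and 144 (4 sulfate libraries alone); read by the treatment text all 3 gave 0. Leaving out a pair or a library gave 0 to 749 genes for cadmium, 0 to 2004 and 0 to 3360 for 50 and 200 µM FeCl3, 0 in each case for the interaction, and 0 to 1 for the salts. DESeq2 size factors and a filter of 1 CPM in 2 libraries left every count at 0. The named genes, most of them chosen for 1 direction throughout, passed the threshold in 61 of 258 values and reversed in 2. Both reversals came with the 4 sulfate libraries alone read by the treatment text, with log2 folds of -1.29 for TraesCS4B01G017600 and 3.61 for TraesCS4A01G334000. The count of genes 2-fold higher with cadmium in every pair was 637 of 25565 and became 1106 of 45669 when a mean of 1 CPM sufficed (lower, 206 and 454). The planned gene list alternatives were not run, because no list could be matched. The labels give no replicate numbers, so no block by replicate was fitted. Depth allowed levels down to about 0.155 to 0.220 CPM.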

Other observations

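The ID neighbours, the thinned comparisons, the cadmium score, the doses of the sulfate libraries and the splits were tests chosen after the results had been seen, while both readings of the sulfate labels were planned and the gene length test was set before its result.

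Read by their title codes, the 4 sulfate libraries and the 6 others together gave 1453 genes past the threshold for cadmium with edgeR, 1012 higher and 441 lower, of which 647 and 282 were at least 4-fold apart. The smallest p values belonged to TraesCS7D01G019400 (log2 fold 4.63 ± 0.31) and TraesCS6A01G387400 (4.26 ± 0.29), both with an adjusted p of 0.00436 and higher in 5 of 5 pairs. On the lower side stood TraesCS5A01G197200 (-3.53 ± 0.33) and TraesCS3B01G278400 (-3.26 ± 0.32), both with an adjusted p of 0.00512. These IDs were picked by their p after their values had been seen. TraesCS7D01G019400 is an ID of subgenome D, which is foreign to a tetraploid wheat, so the source of its counts is uncertain. The calls took 2.56% of the tested subgenome A IDs, 2.84% of subgenome B and 1.08% of subgenome D. Read by the treatment text, the same 10 libraries gave 0 genes with edgeR (3289 at an unadjusted p under 0.05).

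Genes at least 2-fold apart with cadmium at all 3 FeCl3 supplies had consecutive ID numbers more often than shuffled genes. Only IDs with a chromosome and no suffix were used, 22058 in all. Among the 575 of them at least 2-fold higher there were 33 pairs with consecutive numbers, against a mean of 5.56 and a highest value of 14 in 2000 shuffles. Among the 188 at least 2-fold lower there were 8, against a mean of 0.585 and a highest value of 5. The permutation p was 5e-04 for each, the smallest that 2000 shuffles can give. The shuffles treat all genes as exchangeable, and no other gene list was compared, so the excess cannot be tied to cadmium. The longest runs were 3 genes each, on chromosomes 4B (higher) and 2B (lower) by their IDs.

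IDs of subgenome D without a suffix were concentrated in few genes. Between 6178 and 8183 of 35021 had a count in a library, while subgenome A IDs thinned to the same total gave 13774 to 15836. The 100 most abundant D IDs held 39.2% to 46.0% of the D counts, against 15.0% to 19.6% for thinned subgenome A.

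The codes and treatment texts of 3 sulfate libraries contradict each other, and a cadmium score was used to weigh the readings. The score was the mean log2 level of 614 genes minus that of 185, namely those at least 2-fold higher or lower with cadmium in all 3 FeCl3 pairs that also had a mean of at least 5 CPM over all 10 libraries, and it was -1.08 in the library coded B50CK, 2.80 in B50Cd, 2.55 in B200Cd and -0.17 in the sulfate library at 200 µM without cadmium. With genes chosen on the other 2 pairs, it was -0.60 to -0.41 in the FeCl3 series without cadmium and 1.24 to 1.91 with it. The title codes put the cadmium libraries 3.30 above the others (95% bootstrap interval over genes 3.13 to 3.48). The treatment text put them 0.58 below (difference -0.582, interval -0.730 to -0.444). These intervals cover the spread between genes only, not that between libraries, with 2 libraries on each side. By the text, B50CK had cadmium and scored -1.08, while B50Cd had none and scored 2.80. Both scores lay with the libraries of the FeCl3 series that had the opposite cadmium treatment. That argues against the text on cadmium for these libraries, and a mislabelled treatment text is a candidate explanation.

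Dose was weighed by the SD to the FeCl3 libraries, although equal doses of the salts did not supply equal iron. The library coded B50CK, 200 µM by its text, lay nearer the cadmium-free FeCl3 library at 50 µM (0.633) than that at 200 µM (0.828), a difference of -0.195 in favour of the code as a candidate explanation. The sulfate library given as 200 µM without cadmium by both sources lay nearer 200 µM (0.702 against 0.862), but B50Cd, given as 50 µM by both, lay slightly nearer 200 µM with cadmium (0.649 against 0.688). The dose of B200Cd stays open, at 0.615 from 50 µM and 0.619 from 200 µM with cadmium, a difference of 0.0038 that cannot be told apart from none.

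The control stood farthest from the other libraries and also had the lowest total count. With every library thinned to that total, the control's mean SD was 1.22 and the highest of any other library 0.953, which argues against depth. Gene length also argues against a bias of the control, with Spearman's rho of -0.084 across genes between length and its deviation, smaller in size than the -0.229 of the FeCl3 library at 50 µM without cadmium. A response to having neither an added iron salt nor cadmium stays open and untested, because that treatment has 1 library. A difference in how that library was made or handled stays open too.

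Other splits of the libraries were compared by genes at an unadjusted p under 0.05. The 6 libraries of the cadmium test make 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, reached 6624 genes while the highest other gave 6533. With the iron term kept, that other split sets the control against the cadmium library without iron alone. Splits that swap cadmium within the pairs of an iron supply gave 2345, 874 and 444 genes. Those splits, too, are too few for a share under 0.05. For the salts, 16 of 35 splits gave at least the 1803 genes of the real one, so chance was not excluded; these splits ignore dose and cadmium. The highest other split gave 11139 genes, of which 2758 passed the threshold with edgeR, and it follows cadmium by the title codes, which points to a structure of the libraries other than the salts. With dose and cadmium as covariates, salt was also swapped within the 4 matched pairs, which makes 8 splits, too few for a share under 0.05. By the title codes the real split gave 3809 genes, reached by 1 of the 8, and the highest other 3041. By the treatment text it gave 2084, reached by 5 of the 8, and the highest other 8742.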
